A study of Mus musculus with 4 samples.

How the data were processed

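RNA was measured in mouse bone marrow cells sorted as hematopoietic stem cells, the Lin-negative, Sca-1-positive, c-Kit-positive, CD48-negative, CD150-positive gate, per the labels' protocols. Libraries were made with a Smart-seq kit for very small RNA inputs, which copies polyadenylated transcripts along their length. The 4 libraries fall into 2 groups of 2: control libraries from mice with floxed Ddx21 alleles, and knockout libraries from mice that also carry CAG-CreERT2, a Cre recombinase that tamoxifen switches on. Tamoxifen dosing, the time after it and which Ddx21 exons are floxed are not given in the sources used here. The labels do not say whether the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

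The deposited table holds 12390 genes with 1 RPKM value per library (reads scaled by transcript length and library total), a unit identified here from the values. For each gene, value times the length of its longest transcript in GENCODE mouse release M21 was a whole multiple of 1 step per library. A symbol was found for 12381 of the Ensembl gene IDs and a transcript length for 12384. Whole numbers of reads, within a tolerance of 0.1, came out for 99.4% of the values in each library. Reads and fragments cannot be separated this way. The genome build was mm10, per the submitters' processing notes. The aligner, the counter and the handling of reads that match several genes are not given in the sources used here. In the deposited values a gene without reads stands at 0.001, and the lowest maximum over the 4 libraries is 1.0063 RPKM, so genes low in every library were absent from the tests. Gene coordinates are those of GENCODE M21 on the mm10 assembly.

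The recovered reads summed to 55719253 and 62871441 in control replicates 1 and 2 and to 43256639 and 43218008 in knockout replicates 1 and 2. Listed genes held between 99.05% and 99.52% of each library's denominator. To look for repeat copies of a library, the reads of the replicates were compared, with a chi-square per degree of freedom of 48.9 between the control libraries and 152 between the knockout libraries. Neither pair agreed within sampling noise, and each library was counted as a sample, which does not show that they came from separate animals.

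The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(RPKM + 1), over the 11742 genes with a mean of at least 1 RPKM. Genotype was its sole term, which leaves 2 residual degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2(RPKM + 1) scale, knockout minus control, and understate the change of low genes. Errors beside RPKM values are SDs with n = 2 per group, and SEs belong to fold changes. The prior degrees of freedom in this fit were infinite: each gene's own spread was replaced by the trend over all genes, so genes whose replicates lie far apart receive p-values that are too small.

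The design fixed 34 gene lists before the data were examined, and 32 of them had at least 5 tested members. They cover rRNA processing, RNA polymerase I, RNA polymerases II and III, cytosolic ribosomal proteins, snoRNA host genes, p53 targets, core apoptosis genes, DNA repair, DNA replication, mitosis, cell cycle inhibitors, stem cell identity, the sort markers, multipotent progenitors, erythroid, megakaryocyte, neutrophil and monocyte, B cell, T and NK cell, mast cell and basophil, and stroma and endothelium genes. The others cover the interferon response, NF-kB and inflammation, immediate early genes, the integrated stress response, the unfolded protein response, translation factors, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cholesterol synthesis, other DEAD and DEAH box helicases, the spliceosome, and TGF-beta and adhesion genes. Lists were compared with all other genes by camera with a preset correlation of 0.01 and again with the correlation estimated per list, each adjusted over the lists. The preset value treats the genes of a list as nearly independent, so its p-values are too small where list genes vary together between libraries. Fry tested, with the same adjustment, whether a list's own genes move on balance in one direction, which does not compare them with other genes. Camera with an estimated correlation and fry both rest on the 2 residual degrees of freedom. Almost no list can pass there after adjustment over 32 lists, so a high adjusted p does not argue against a list.

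The rule for named genes was also fixed beforehand. It takes Ddx21 and its paralog Ddx50, then the 10 largest changes in each direction among called genes with a mean log2 CPM of at least 3, non-overlapping groups and a symbol that is not a clone, predicted or pseudogene name. It adds up to 3 called members of each list, 2 uncalled members where a list has none called, for lists past the set test and for rRNA processing, p53 targets and stem cell identity, and the 4 sort markers. It gave 69 genes, not all of which are reported here. Other genes named were chosen after their values were seen.

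Alternatives chosen before the data were examined were TMM-type rescaling (the trimmed mean of log ratios, with 30% of ratios and 5% of levels trimmed at each end), no filter on the mean, pseudocounts of 0.1 and 5, the replicate number as a block, each library left out, a log2 fold change of at least 1, an estimated correlation, and fry. Alternatives added after seeing the data were limma voom on the recovered reads, with and without rescaling, with robust moderation and with totals over the tested genes, plus median centring, quantile normalization, robust moderation of the rescaled values, and an estimated correlation on rescaled values.

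The scripts were tested on simulated reads, in 5 draws of 4 libraries with 200 changed genes. With the library shift seen here, the test on unscaled values recovered 49.6% of 2-fold and 99.1% of 4-fold changes, with 16.8 false calls per draw. After rescaling it recovered 97.3% of 2-fold and 100% of 4-fold changes, with 19.6 false calls per draw. The false calls exceed the nominal 5% of calls, and the simulated genes shared 1 dispersion of 0.012, which real genes do not. In the real data the rescaled fit had 3.64 prior degrees of freedom and called 0 genes, so these recovery rates do not apply to it. Figures were drawn with matplotlib 3.10.9.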

Results

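RNA levels were compared between 2 control and 2 Ddx21 knockout libraries of mouse bone marrow cells sorted as hematopoietic stem cells. The comparison asks what loss of Ddx21, a nucleolar DEAD box RNA helicase, changes in the sorted cells. Myeloid transcripts such as Elane and S100a8 were among the most abundant, so changes cannot be assigned to stem cells alone. The libraries held between 43218008 and 62871441 recovered reads. Values are RPKM with SD (n = 2 per group), fold changes are log2 with SE, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 11742 genes.

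Ddx21 itself (ENSMUSG00000020075, chromosome 10, 62580251 to 62602281, minus strand, mm10) stood at 11.0 and 12.1 RPKM in the control libraries and at 6.20 and 6.60 RPKM in the knockout libraries. Its mean was 11.5 ± 0.817 RPKM in control and 6.40 ± 0.286 RPKM in knockout, a log2 fold change of -0.76 (SE 0.30, adjusted p = 0.158), lower in both knockout libraries but short of the threshold. Its paralog and neighbour Ddx50 (chromosome 10, 62615895 to 62651218) had a log2 fold change of 0.38 (SE 0.24, adjusted p = 0.385). The values cover the whole gene, and single exons were not analysed here. After rescaling the log2 fold change was -1.10 (adjusted p = 0.103), and voom on rescaled reads gave an adjusted p of 0.0400. Without knockout replicate 1 it was 0.0180, in a setting that called 6381 genes higher and 526 lower.

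Across all genes, 391 were higher and 101 lower in the knockout libraries, of which 328 and 66 were protein-coding. Cdkn1a, the cell cycle inhibitor p21, rose from 2.35 ± 0.359 to 47.9 ± 23.2 RPKM (log2 fold change 3.78, SE 0.28, adjusted p = 2.46e-39). Phlda3, a p53-induced inhibitor of Akt, rose from 0.744 ± 0.243 to 20.9 ± 11.0 RPKM. The bone matrix genes Bglap, Bglap2, Col1a1, Col1a2, Sparc and Dcn also rose, with log2 fold changes from 3.05 for Dcn to 3.35 for Bglap, together with Dglucy (2.87) and Mmp2 (2.80). Among called genes with a mean log2 CPM of at least 3, non-overlapping groups and a symbol that is not a clone, predicted or pseudogene name, the 10 largest decreases were Il1b (-1.12), H2-Q10 (-1.11), Lcn2 (-1.06), S100a8 (-1.04), S100a9 (-1.03), Camp (-1.01), Ltf (-0.99), Rpe (-0.97), Ngp (-0.97) and Tuba4a (-0.94), most of them genes abundant in neutrophils. Bglap and Bglap2 are near-identical copies, so their separate values are uncertain.

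The count of called genes depended on how the libraries were scaled. The median log2 fold change of all tested genes was 0.31 in the deposited values, with medians over all genes of 0.12 and 0.50 above the control mean in knockout replicates 1 and 2, and -0.01 after TMM-type rescaling. After rescaling, limma called 0 genes in either direction, with a smallest adjusted p of 0.0547 (Cdkn1a), while 876 genes were higher and 934 lower at an unadjusted p under 0.05, and voom on rescaled reads called 34 higher and 13 lower. All 391 and 101 called genes kept their sign after rescaling, which could hardly come out otherwise. Rescaling lowered folds by less than a call required, and it could only deepen the decreases. Without control replicate 1 the counts were 37 and 5, without control replicate 2 27 and 9, without knockout replicate 1 6381 and 526, and without knockout replicate 2 96 and 13. The groups did not overlap for 62.9% of tested genes, and for 54.6% after rescaling, against 33.3% by chance without a shift between libraries.

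Of 30 tested p53 target genes, 21 rose, 0 fell and 9 were not called, and 25 rose when adjusted over the list alone, with a median log2 fold change of 1.13. Beside Cdkn1a and Phlda3, Ccng1, a cyclin G induced by p53, rose from 13.3 ± 0.379 to 53.6 ± 18.1 RPKM (log2 fold change 1.89, SE 0.22, adjusted p = 8.73e-15). Among members chosen after their values were seen, the pro-apoptotic gene Bax rose from 30.1 ± 1.29 to 82.1 ± 13.5 RPKM, the secreted factor Gdf15 by 2.15 on the log2 scale, Zmat3 by 1.89, Perp by 2.18, the death receptor Fas by 1.41, and Mdm2, the ubiquitin ligase that limits p53, by 0.82. The 9 members not called included Aen (0.82, adjusted p = 0.0503), Xpc (0.01) and Plk3 (-0.08). Camera placed the list above other genes (adjusted p = 1.47e-33). With an estimated correlation, on 2 residual degrees of freedom, the adjusted p was 0.422. After rescaling the median was 0.81 and 27 of the 30 members stayed higher; limma then called 0 of them and voom on rescaled reads 10. Leaving out a library gave 4 called members without control replicate 1, 4 without control replicate 2, 28 without knockout replicate 1 and 8 without knockout replicate 2.

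**Figure D1:**
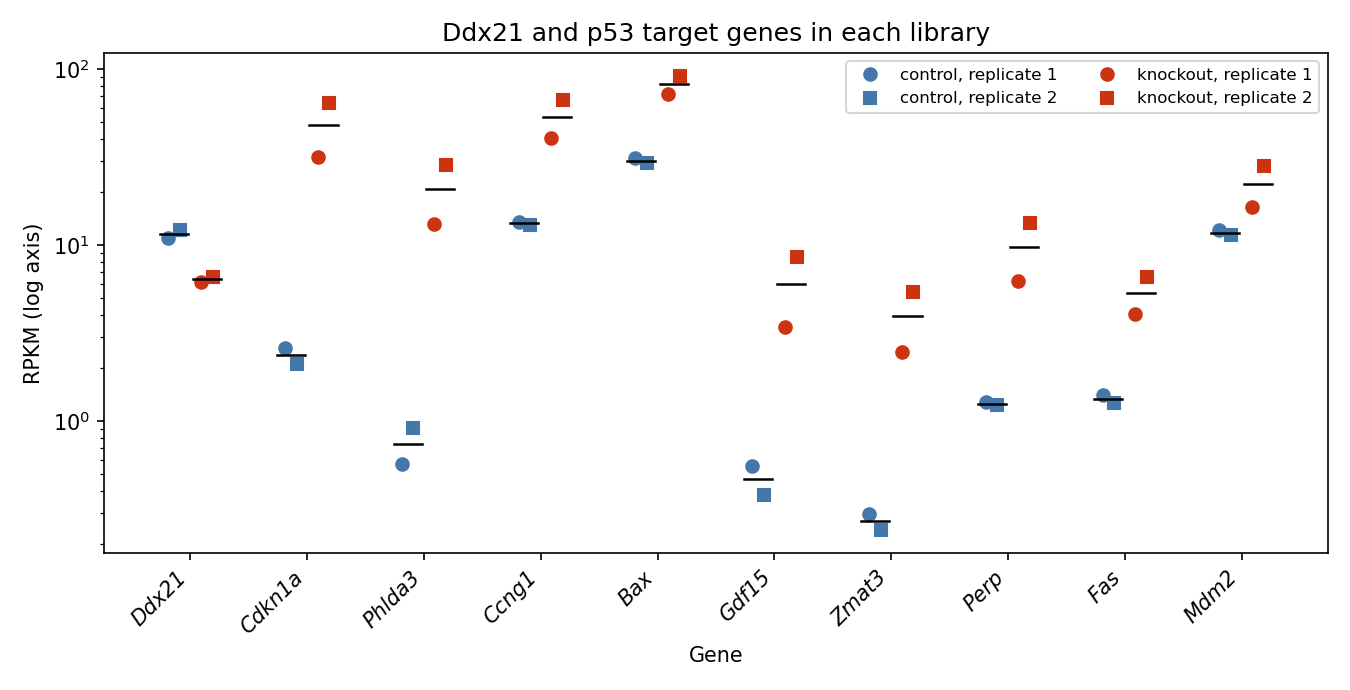
RPKM (log axis) of Ddx21 and 9 p53 target genes in each of the 4 libraries, with circles and squares for replicates 1 and 2, blue for control, red for knockout, and a black line at each group mean. Both knockout libraries lie below both controls for Ddx21 (6.20 and 6.60 against 11.0 and 12.1 RPKM) and above them for each p53 target, as for Cdkn1a (31.5 and 64.3 against 2.61 and 2.10 RPKM).

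Genes of ribosome production, in which Ddx21 takes part, were compared next. Of 64 rRNA processing genes 0 rose and 0 fell, with a median log2 fold change of 0.21, below the 0.31 of all genes. The smallest p-values belonged to Nob1, an endonuclease of 18S rRNA maturation (0.46, SE 0.21, adjusted p = 0.253), and Rcl1 (0.40, SE 0.20, adjusted p = 0.307), neither past the threshold. Camera gave an adjusted p of 0.541 for this list on the deposited values and 9.06e-04, toward lower, after rescaling, where the adjusted p was 0.799 with an estimated correlation. Of 15 RNA polymerase I genes, 23 genes of RNA polymerases II and III, 38 spliceosome genes and 41 other DEAD and DEAH box helicases 0 were called, and their camera adjusted p-values were 0.541, 0.617, 0.0817 and 0.823. The 79 cytosolic ribosomal protein genes had a median of -0.09, with 0 called; Rpl24 (0.53, adjusted p = 0.340) and Rpl22 (0.28, adjusted p = 0.396) had the smallest p-values, and Rpl22 turned to -0.10 after rescaling. Camera placed this list below other genes (adjusted p = 2.97e-11; 0.753 with an estimated correlation), which was lost without knockout replicate 2 (0.609) and turned toward higher with quantile normalization. Pseudogene copies make single ribosomal protein values uncertain. The snoRNA host genes (median 0.41, 0 of 12 called, 2 higher when adjusted over the list alone) had a camera adjusted p of 0.216, and 0.0245 without control replicate 1. The spliceosome list had 5.13e-04 after rescaling (adjusted p = 0.799 with an estimated correlation) and 0.0106 without control replicate 1, both toward lower. Without knockout replicate 1, members of each of these lists were called, mostly higher, apart from the ribosomal protein genes, which were mostly lower. Most of all tested genes were called higher in that setting, where the remaining knockout library carries the largest shift. The higher calls there do not show a rise particular to these lists.

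Of 31 stem cell identity genes 8 rose and 0 fell, 16 when adjusted over the list alone, with a median of 0.68. The cytokine gene Ltb rose from 4.46 ± 0.671 to 13.7 ± 0.512 RPKM (log2 fold change 1.44, SE 0.31, adjusted p = 2.29e-04), and Pdzk1ip1 rose by 1.06. Of 19 megakaryocyte genes 7 rose, 14 over the list alone, with a median of 0.77, among them the platelet factor gene Pf4 (0.76, SE 0.16, adjusted p = 2.53e-04) and the thrombin receptor gene F2rl2 (1.43). Of the sort markers, Ly6a, which encodes Sca-1 (0.52, adjusted p = 0.0557), Kit (0.38, adjusted p = 0.305), Slamf1, which encodes CD150 (0.82, adjusted p = 0.161), and Cd48 (0.14, adjusted p = 0.667) were not past the threshold, although 2 of the 4 were higher when adjusted over the list alone, and Cd48 turned to -0.23 after rescaling. In this CD48-negative gate Cd48 stood between 20.7 and 32.4 RPKM over the libraries, and Slamf1 between 3.85 and 10.3 RPKM. RNA levels do not show surface protein, and the purity of the sort was not tested. Camera adjusted p-values for the stem cell and megakaryocyte lists were 3.12e-08 and 3.53e-08, and with an estimated correlation 0.706 and 0.653. After rescaling the medians were 0.36 and 0.42 and limma called 0 members of either list. Leaving out either control library also called 0 members of both, while 30 stem cell and 18 megakaryocyte genes were called without knockout replicate 1, and 1 and 0 without knockout replicate 2.

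Of 25 neutrophil and monocyte genes 12 fell and 0 rose, 16 when adjusted over the list alone, with a median of -0.69. The antimicrobial gene Lcn2 fell from 359 ± 45.8 to 171 ± 1.52 RPKM (log2 fold change -1.06, SE 0.16, adjusted p = 2.54e-08), and Camp and Ltf fell with it. Of 18 multipotent progenitor genes 8 fell and 2 rose: Ms4a3 (-0.87), Plac8 (-0.75) and Wfdc17 (-1.27) fell, as did the granule genes Elane, Mpo, Ctsg and Prtn3 and the chaperone Calr, chosen after their values were seen, while Cd27 (0.71) and Cd34 (0.63) rose. Adjusted over the list alone, 8 fell and 4 rose. These granule transcripts were abundant in all libraries, Elane at 19680 ± 161 RPKM in control and 11900 ± 3725 RPKM in knockout. The neutrophil and monocyte list held 2.12% and 2.06% of recovered reads in the control libraries and 1.37% and 0.893% in the knockout libraries. Camera adjusted p-values were 7.16e-35 for the neutrophil and 4.45e-10 for the progenitor list, 0.304 for both with an estimated correlation, and 0.0766 for the progenitor list after rescaling. Without control replicate 1, control replicate 2, knockout replicate 1 and knockout replicate 2, the neutrophil members that fell numbered 1, 3, 11 and 3, and the progenitor members 0, 0, 8 and 1, with 4 progenitor members higher without knockout replicate 1 and 0 otherwise.

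Of 8 tested members of the stroma and endothelium list 5 rose, namely Bglap, which encodes osteocalcin, Sparc, Col1a1, Col1a2 and Alpl. These 5 were higher in both knockout libraries, most of all in replicate 1. The list median was 2.55, and 7 members rose when adjusted over the list alone. Bglap stood at 181 and 84.4 RPKM in the control libraries, 2504 RPKM in knockout replicate 1 and 644 RPKM in knockout replicate 2. The endothelial gene Pecam1 (0.67, adjusted p = 0.187), Emcn (0.75, adjusted p = 0.219) and Vcam1 (-0.35, adjusted p = 0.360) were not past the threshold. This list held 0.0906% and 0.0746% of recovered reads in the control libraries and 1.04% and 0.311% in the knockout libraries. Camera gave an adjusted p of 2.59e-83, and 0.181 with an estimated correlation. After rescaling limma called 0 members, since the SE grew while the folds stayed large (Bglap 2.96, SE 0.82, against 3.35, SE 0.16). Camera on rescaled values gave an adjusted p of 2.36e-04, a call not held there with an estimated correlation. The camera call was lost without knockout replicate 1 (0.0695).

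**Figure D2:**
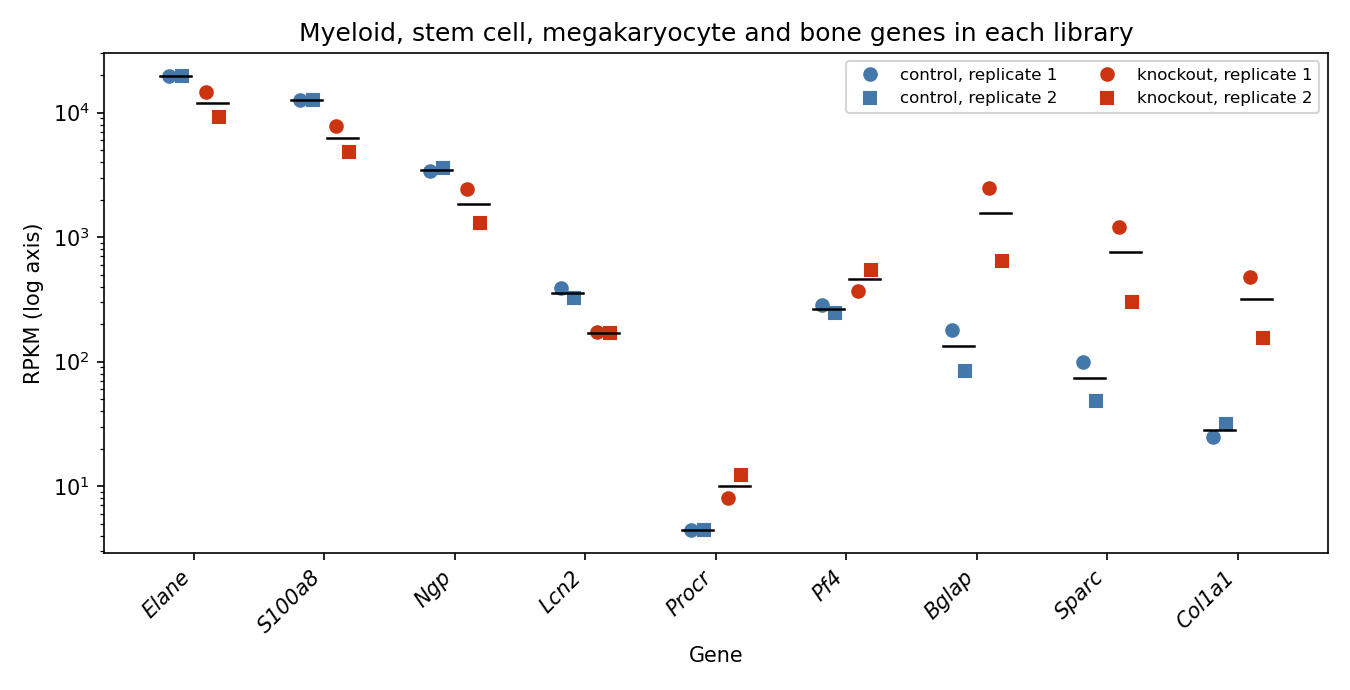
RPKM (log axis) of myeloid, stem cell, megakaryocyte and bone genes in each of the 4 libraries, with circles and squares for replicates 1 and 2, blue for control, red for knockout, and a black line at each group mean. Elane, S100a8, Ngp and Lcn2 are lower and Procr, Pf4, Bglap, Sparc and Col1a1 higher in both knockout libraries, and Bglap lies at 2504 RPKM in knockout replicate 1 against 644 RPKM in replicate 2.

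Of 14 cell cycle inhibitors 4 rose and 0 fell, 5 when adjusted over the list alone, with Txnip from 77.6 ± 12.7 to 190 ± 36.7 RPKM (log2 fold change 1.28, SE 0.17, adjusted p = 6.43e-11) and the antiproliferative gene Btg2 (0.89) beside Cdkn1a. Of 40 mitosis genes 1 fell, the ubiquitin-conjugating enzyme gene Ube2c (-0.59, SE 0.17, adjusted p = 0.0170), and the list median was 0.03, with 2 of the 40 members above the median of all genes. Of 43 DNA replication genes and 34 DNA repair genes 0 were called, with a camera adjusted p of 0.979 for DNA repair. Camera adjusted p-values were 9.69e-07 for the inhibitors and 4.98e-05 for mitosis, and 0.653 and 0.886 with an estimated correlation; DNA replication had 0.374, and 0.00281 toward lower after rescaling, where the adjusted p was 0.799 with an estimated correlation. Mitosis genes differed between the knockout libraries, with medians of -0.25 and 0.34 against the control mean in replicates 1 and 2. The medians of all genes there were 0.12 and 0.50, so mitosis genes lay below them in both libraries. The camera call was lost for mitosis without knockout replicate 1 (0.535), where 15 members were called higher, and for the inhibitors without knockout replicate 2 (0.0687), and DNA replication had 0.0186 without knockout replicate 1. The inhibitors called without control replicates 1 and 2 and knockout replicates 1 and 2 numbered 2, 2, 10 and 1.

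Of 38 interferon response genes 6 rose and 0 fell, 15 over the list alone, among them the GTPase genes Iigp1 (1.02, SE 0.28, adjusted p = 0.0105), Igtp (0.76) and Gbp2 (0.94). Of 19 immediate early genes 5 rose, 10 over the list alone, among them Jun (0.78, SE 0.19, adjusted p = 0.00291) and Ier2 (0.60). Camera adjusted p-values were 8.73e-05 and 0.00125, and 0.886 and 0.653 with an estimated correlation. In the NF-kB and inflammation list Icam1 (1.07) and Ier3 (0.78) rose and Il1b fell, with 17 of 20 members not called and a camera adjusted p of 0.979. The integrated stress response list had 3 of 24 members higher, Sesn2 (1.59), Ddit4 (1.51) and Ppp1r15a (0.98), the first 2 of which are also on the p53 list, and a camera adjusted p of 0.677. Core apoptosis genes (0 of 25 called) and the TGF-beta and adhesion list, where Icam1 rose alone of 20, had camera adjusted p-values of 0.650 and 0.772. After rescaling limma called 0 members of the interferon and immediate early lists, as it did without either control library or knockout replicate 2. Without knockout replicate 1, 34 interferon and 12 immediate early genes were called higher, and the camera call of the immediate early list was lost (0.302).

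In the unfolded protein response list 2 of 24 members fell, the chaperone Calr (-0.60, SE 0.16, adjusted p = 0.0110) and Sdf2l1 (-0.54), the latter with overlapping groups, and 3 fell when adjusted over the list alone. Of 22 glycolysis genes 3 fell, Pgam1 (-0.63, SE 0.16, adjusted p = 0.00539), Eno1 (-0.55) and Gpi1 (-0.50), while over the list alone 4 fell and 1 rose. In the oxidative phosphorylation list 0 of 74 were called, including Ndufs1 (0.28, -0.09 after rescaling) and Atp5b (-0.23), and 0 of 13 mitochondrially encoded genes, including mt-Atp6 (-0.42) and mt-Atp8 (-0.38), whose gene overlaps that of mt-Atp6. None of the 41 translation factor genes was called. The members with the smallest p-values were Eif4a2 at 0.47 and Eif2b2 at 0.43, and they stood at 0.09 and 0.06 after rescaling. The translation factor list held 2.715% and 2.758% of recovered reads in the control libraries and 2.649% and 2.371% in the knockout libraries. Camera adjusted p-values for these lists in that order were 1.15e-08, 8.73e-05, 4.46e-05, 1.89e-07 and 0.00628, and with an estimated correlation 0.4997 for the first and 0.422 for the others. Quantile normalization ended the calls of the oxidative phosphorylation, mitochondrially encoded and translation factor lists, and the translation factor call was also lost without control replicate 2 (0.118) and knockout replicate 2 (0.0896), and that of oxidative phosphorylation without knockout replicate 2 (0.0545). Without either control library or knockout replicate 2, 0 protein folding and glycolysis members were called, and without knockout replicate 1 6 and 7 were lower and 2 and 7 higher.

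Markers of the other blood lineages gave mixed values. Of 20 erythroid genes Gata1 (0.79) and Hemgn (0.83) rose and the globin gene Hbb-bs (-0.78) fell. The list of 12 mast cell and basophil genes also holds eosinophil granule genes. Its called members, Epx (0.58) and Prg3 (0.57), are of this kind and rose with overlapping groups. Members not called included Cpa3 (0.49), Prss34 (0.08), Mcpt8 (-0.14) and Hdc (-0.285). Of 3 tested T and NK cell genes Nkg7 fell (-0.65), while Ccl5 (0.69) and Lck (0.70) were higher and not called. In the B cell list 0 of 7 were called. The camera adjusted p-values were 0.868 for erythroid, 0.839 for mast cell and basophil and 0.541 for B cell genes, and cholesterol synthesis genes (0 of 22 called) had 0.839. Adjusted over the list alone, 4 erythroid genes rose and 3 fell, and 3 B cell genes rose. Rescaling with limma left 0 called members in each of these lists. Camera called the erythroid list higher without control replicate 1 (0.00114) and lower without control replicate 2 (3.48e-04) and knockout replicate 1 (0.00186), and mast cell and basophil genes likewise (4.06e-05, 5.70e-04 and 0.0372).

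**Figure D3:**
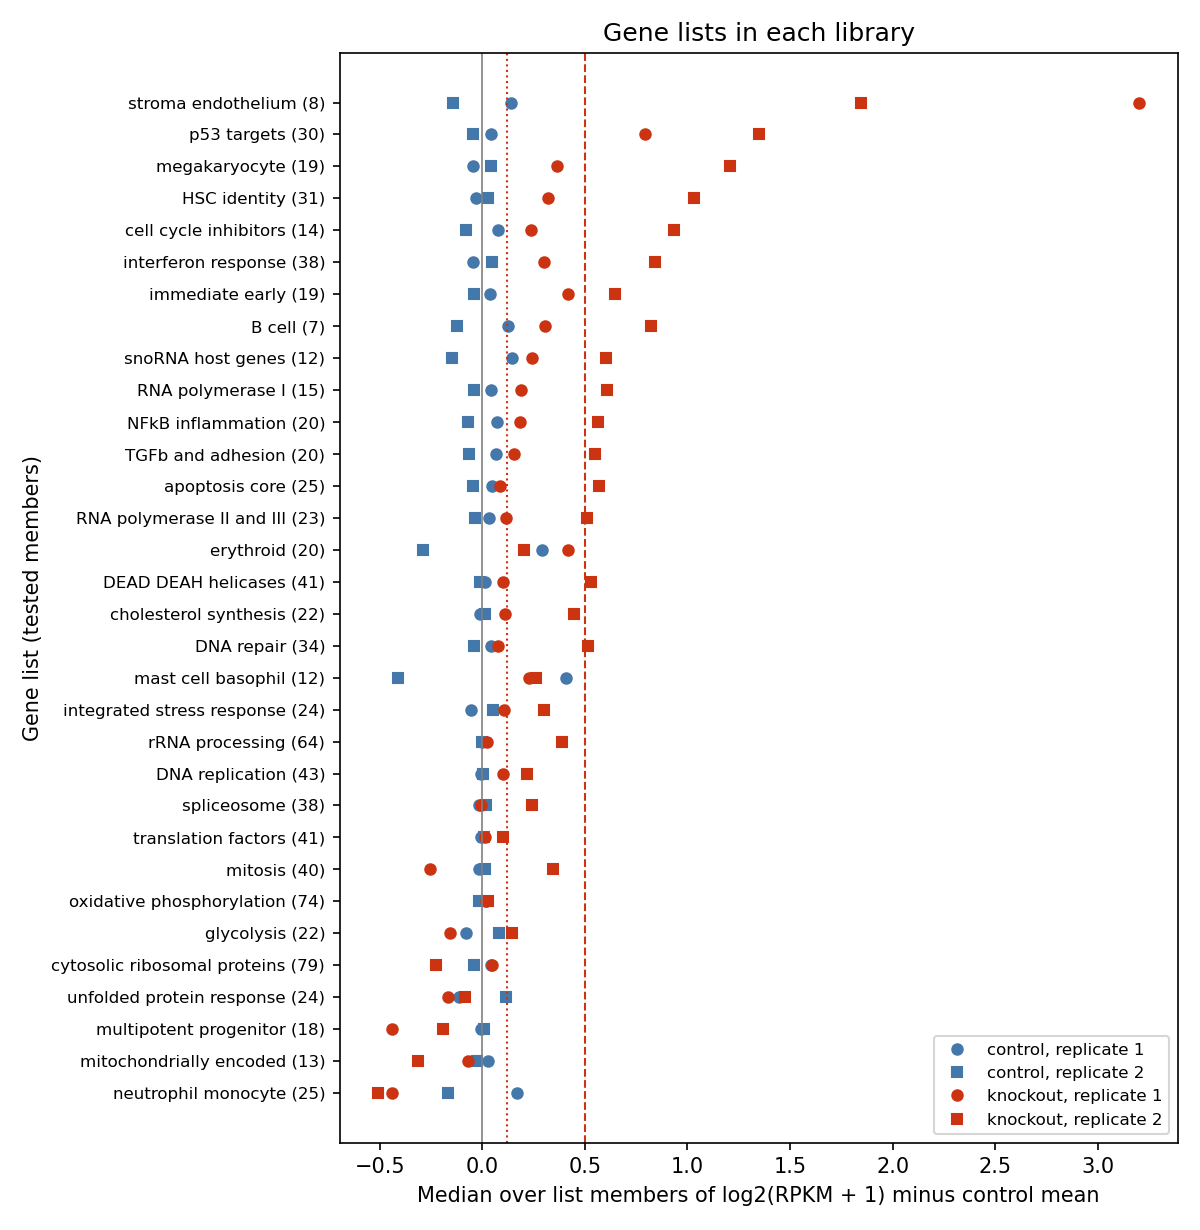
Median over the tested members of each gene list of log2(RPKM + 1) minus the control mean, in each of the 4 libraries, with the number of tested members in brackets and red vertical lines at the medians of all genes in knockout replicates 1 (dotted, 0.12) and 2 (dashed, 0.50). The p53 targets lie at 0.80 and 1.35 in knockout replicates 1 and 2, and the neutrophil and monocyte genes at -0.44 and -0.51.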

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

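The scaling of the libraries, the moderation of the spread and single libraries set the gene counts, while 16 lists passed camera with a preset correlation and between 12 and 20 did under the other scalings, filters, pseudocounts and left-out libraries. The preset correlation treats the genes of a list as nearly independent, so a similar count of lists does not show that the lists hold. The erythroid call, for example, changed direction with the control library left out. Of the settings below, voom, median centring, quantile normalization, robust moderation and an estimated correlation on rescaled values were chosen after seeing the data. Against 391 genes higher and 101 lower, TMM-type rescaling, median centring and quantile normalization each gave 0 and 0. Rescaling removes the shift between libraries, and the prior degrees of freedom then fell from infinite to 3.64, so that each gene's own spread counted. The fold of Cdkn1a was 3.78 (SE 0.28) before and 3.46 (SE 0.20) after, and 21 genes higher and 9 lower had an adjusted p under 0.1. Rescaling with robust moderation gave 3 and 0, voom on rescaled reads 34 and 13 (33 and 6 of them among the genes called without rescaling), the same with robust moderation 66 and 49, and with totals over the tested genes 20 and 7. Unscaled voom gave 364 and 83. No filter on the mean gave 439 and 114, pseudocounts of 0.1 and 5 gave 402 and 107, and 350 and 94, and a log2 fold change of at least 1 gave 219 and 28. Leaving out 1 library gave between 27 and 6381 genes higher and between 5 and 526 lower, the lone library being assumed to vary like the other group; without knockout replicate 1 the remaining knockout library carries the largest shift.

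With the replicate block the counts were 175 and 64. Same-numbered libraries deviated with a correlation of 0.0668 over genes. This value does not exclude a shared litter or day, on which the labels say nothing.

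With an estimated correlation 0 lists passed (smallest adjusted p 0.181), with fry 0 (smallest 0.406), and with an estimated correlation on rescaled values 0 (smallest 0.766). These tests rest on the 2 residual degrees of freedom, so this outcome was close to fixed and does not argue against the lists. The log2 fold change of Ddx21 stayed negative in every setting run, with adjusted p-values from 0.0173 to 0.957. It crossed the threshold without knockout replicate 1, as given in the report, where leaving out 1 library moved it between -0.83 and -0.69. With voom on rescaled reads it was -1.24 (0.0400), with robust moderation -1.24 (0.0173) and with totals over the tested genes -1.24 (0.0401). Of the other 68 named genes, all 53 that had been called lost their call with rescaling. The rest were called neither before nor after it, and of these 12 kept their sign and 3 changed it. Rpl22 was -0.10 with rescaling, with or without robust moderation, -0.0763 with median centring, -0.0635 with voom on rescaled reads, with or without robust moderation, and -0.0625 with totals over the tested genes. Ndufs1 was -0.0918 with rescaling, with or without robust moderation, -0.0733 with median centring, -0.0828 with voom on rescaled reads, with or without robust moderation, and -0.0817 with totals over the tested genes. Cd48 was -0.23 with rescaling, with or without robust moderation, and with voom on rescaled reads in each form, -0.22 with median centring, -0.11 with quantile normalization, and between -0.12 and 0.41 with 1 library left out, negative without control replicate 2 (-0.12) and without knockout replicate 2 (-0.0718). The cause was not tested beyond the scaling itself. A comparison with adjusted p-values deposited with the table was planned and not run, since the columns used here hold none. At 43218008 recovered reads or more per library, between 15 and 41 of the 12390 genes stood at the value of a gene without reads, where depth sets the limit.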

Other observations

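All tests and gene groups in this part were chosen after the results were seen. Several genes outside the p53 list that rose are, as background, known or proposed p53 targets: Ak1 had a log2 fold change of 2.41 after rescaling, Psrc1 of 2.15, Dcxr of 1.72, Ephx1 of 1.97, Sulf2 of 1.86 and Gtse1 of 0.85. Voom on rescaled reads called Ak1 (adjusted p = 0.0216), Psrc1 (0.0148), Dcxr (0.0456), Ephx1 (0.0444) and Sulf2 (0.0148), and not Gtse1 (0.135). Of 8 tested Gimap genes, GTPases of lymphocytes and stem cells that lie side by side on chromosome 6, 6 rose and 0 fell, with a median of 0.94, and 0.65 after rescaling; their sequences are alike, so reads may be shared. After rescaling limma called 0 of the 8 and voom 2, Gimap6 (0.94, adjusted p = 0.0499) and Gimap3 (1.38, 0.0499), and not, for example, Gimap5 (0.0707) or Gimap1 (0.245). Of 8 MHC class II genes 1 rose, H2-Eb1, at 0.80 after rescaling.

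The clustered histone genes, whose messages mostly lack a poly(A) tail, had 0 of 51 called in either direction, yet 44 of the 51 were lower after rescaling, with a median of -0.57. Immunoglobulin variable and constant genes had 4 of 15 higher and 4 lower, some of them with nearly all reads in 1 library. Ighv1-12 had 14, 0, 1896 and 0 recovered reads in control replicates 1 and 2 and knockout replicates 1 and 2, and Ighg2b had 88, 24, 5365 and 21. The cartilage gene Matn1 had 4, 0, 185 and 548 reads in the same order, highest in the knockout library with less bone RNA.

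The rise of the p53 targets was weighed against 3 technical explanations. The scaling shift as the whole cause is argued against by the median after rescaling, 0.81 (95% bootstrap interval over genes 0.49 to 1.16). Carried-over bone RNA would put these genes higher in knockout replicate 1, but their median log2 ratio of replicate 1 to 2 was -0.28 (-0.43 to -0.20). A larger stem cell share would raise them as much as the stem cell genes if they were equally enriched in stem cells. Their median lay 0.44 above that of the stem cell genes (0.10 to 0.83). That enrichment was not measured and the interval covers genes, not libraries, so a larger share is not excluded. A p53 response to Ddx21 loss or to Cre activity remains as a hypothesis; no Cre control without floxed alleles was analysed here, so these stay open.

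For the neutrophil genes the median after rescaling was -1.03 (-1.21 to -0.45). Rescaling lowered knockout values relative to control, so it could only deepen their fall and does not test scaling as its cause. The 12 members with at least 100 RPKM in control had log2 fold changes between -1.45 and -0.78, with an SD of 0.25. These are group means, and the members did not keep 1 ratio between the knockout libraries. Ngp stood at 2417 and 1296 RPKM in knockout replicates 1 and 2, Lcn2 at 172 and 170, and Retnlg at 107 and 170. A single smaller share of myeloid RNA was therefore not shown and stays open. The fall may reflect cells or free RNA passing the gate, which should exclude mature neutrophils, or lower expression within the sorted cells. These were not separated.

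The bone genes may reflect RNA of bone cells carried into the knockout libraries, though the gate should exclude such cells. The log2 ratio of replicate 1 to 2 had a median of 2.22 over the 5 called list members (SD 0.52), from 1.17 for Alpl to 2.45 for Sparc, and was 1.52 for Ibsp, 1.27 for Serpinf1, 1.04 for Col2a1 and 0.71 for Mmp2, so 1 source in a fixed ratio was not shown and stays open. Whether marrow stroma of every type was carried over also stays open: only 3 of the 15 niche and endothelial genes looked for were tested, Pecam1, Emcn and Vcam1, with a median of 0.32 after rescaling. A change of these genes within the sorted cells stays open.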
